A study of Arabidopsis thaliana with 22 samples.

How the data were processed

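Leaves of Arabidopsis thaliana Col-0 plants at growth stage 3.90 were measured over a day of 12 h light and 12 h dark, per the labels. Samples stood at 11 time points (0, 1, 2, 4, 8, 12, 13, 14, 16, 20 and 24 h) with 2 biological replicates each, 20 plants pooled per sample, giving 22 Affymetrix ATH1 arrays. The hours were taken from the source names. For 4 arrays another label gives a different hour: the age tag reads 5 h for both arrays called 8 h here and 14 h for both called 16 h. The replicate 2 titles name 8 h and 16 h for these arrays, like the source names. The labels do not say in words whether 0 h was the start of the light or of the dark. The number in the replicate 1 titles runs from 21 at 0 h over 5 at 8 h to 21 at 24 h.

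The authors' deposited table holds linear probe set intensity values, 1 column per array. From the values, the mean without the lowest and highest 2% was 100 on every array, so each array had been scaled to a common mean by the authors. The software used is not given in the sources used here. The table holds 22810 probe sets, of which 64 are controls and 22746 are not. The platform annotation given for this work named 1 gene for 13513 of these, several for 503 and none for 8730, which are unnamed here. Symbols were updated from the RefSeq gene table of assembly TAIR10.1, and genes without a symbol are given by locus code. No gene was named from a probe set with several genes.

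Values were used as scaled by the authors and transformed to log2(value + 4.01), the pseudocount being 10% of the median of all values (40.1). Log2 differences on this scale understate the change of low genes. The 60% of probe sets with the highest mean over all arrays were tested, 13648 in all, of which 7380 stood for 1 named gene (7303 genes). Where several probe sets stood for a gene, the one with the highest mean was named. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with 1 mean per time point, 11 residual degrees of freedom and Benjamini-Hochberg adjustment over the 13648 probe sets, all tests being two-sided. Every adjusted p of a gene is from limma. Compared were all time points jointly, the mean of the 13 to 24 h arrays against the mean of the 1 to 12 h arrays, 1 to 12 h against 0 h, 13 to 24 h against 12 h, and 24 h against 0 h. A cosine wave with a period of 24 h was fitted over the hours to find daily rhythms. A probe set passed at an adjusted p under 0.05. Values are given as log2 difference ± standard error (SE) from the fit, with n = 2 arrays per time point, or as mean intensity ± SD with n = 2.

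Before the data were examined, 31 gene lists with 466 genes were fixed. Named probe sets covered 74 of these genes, and 65 were kept by the filter. The 12 lists with at least 3 kept genes were tested with camera (correlation preset at 0.01) in 4 comparisons, adjusted over all tests. Kept were 3 of 18 starch synthesis, 4 of 26 starch breakdown, 4 of 18 sucrose synthesis and 4 of 20 darkness and low-sugar genes. For the photosystem 5 of 27 were kept, for the Calvin cycle 4 of 23 and for cold and abscisic acid 6 of 17. A list result covers its kept genes only, not the whole pathway. Named genes were taken from fixed groups, and not every member of a group is named. Per comparison these were the 10 largest rises and 10 largest falls among genes that passed and moved the same way in both replicate series. The others were members of the lists on starch, sucrose and the clock, up to 4 members of every other list, and reference and root genes. For the time course and the rhythm, some of the genes with the 20 largest ranges or waves are named, with members of the lists.

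Samples of the same replicate number deviated together from their time point means. The correlation of the replicate differences over the 55 pairs of time points ran from 0.125 to 0.628 (median 0.398), all above 0.1. The pairing comes from the replicate numbers in the labels. The counts with the replicate number as a block are given where they differ by over 1.5 times. The tests were checked on simulated data drawn from the real means and spread with 200 changed probe sets among 13648. Of 50 probe sets changed 2-fold (1 on the log2 scale), 46 were recovered between the 2 parts of the cycle. At 1 h against 0 h 22 were recovered, and as a daily rhythm 40. The joint test of all time points recovered 12 of the 50 changed at 1 h alone, which is not its recovery of a change over several hours. At 2 on the log2 scale the recovered numbers were 50, 47 and 49, and 38 by the joint test. The simulated arrays varied independently of one another, unlike the real replicate series. The number of arrays limits the precision.

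Alternatives planned before the data were examined were no pseudocount, a pseudocount equal to the median, no filter, the upper 40% of probe sets, quantile normalization, equal array medians, the replicate block, array weights, eBayes without a trend, each array left out in turn, 2 harmonics, the hours of the age tag, 0 h and 24 h merged, an estimated correlation in camera, and all probe sets of a gene averaged. Added after seeing the data were the actin 3' to 5' ratio as a covariate, leaving out the 3 arrays with the highest ratio, and leaving out the 8 h and 16 h arrays.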

Results

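Transcript levels in Arabidopsis leaves were followed over 24 h of a light and dark cycle, in a study of gene expression and carbohydrate metabolism, on 22 arrays with 2 per time point. The median intensity per array ran from 37.6 to 44.7, and the 2 arrays of a time point correlated with r between 0.943 and 0.966 across probe sets, which are not independent replicates. The first component held 31.9% of the variance and the second 17%, both mostly between time points. The third held 13.1%, of which 77.0% lay between the replicate series. RNA quality differed between these series. The ratio of 3' to 5' actin signal was 1.85 ± 0.28 (SD, n = 11) in replicate series 1 and 3.20 ± 1.21 (SD, n = 11) in series 2, highest at 6.31 in the 1 h array of series 2.

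Over the whole cycle, GI, an evening gene of the circadian clock, ranged from 8.65 ± 9.26 at 8 h to 657 ± 78 (SD, n = 2) at 20 h. EXO, a gene linked to leaf growth, was highest at 1 h (912 ± 5.2) and lowest at 20 h (14.0 ± 11.7; SD, n = 2). Of the cold-regulated genes COR27 and COR28, the former was highest at 1 h (277 ± 86) and lowest at 14 h (1.05 ± 0.35), and the latter lowest at 16 h (0.80 ± 0.28) and highest at 20 h (204 ± 59; SD, n = 2). AT2G15020 was at 0.55 ± 0.21 at 2 h and 445 ± 23 at 13 h (SD, n = 2; adjusted p = 1.0e-08). Such low levels are not clearly above background, since bacterial control probe sets had a median of 2.00 and a highest value of 29.2. The sizes of log2 differences from or to levels under 29.2, here and below, therefore depend on the pseudocount and give no order among genes. The range of AT2G15020 was 6.62 on the log2 scale, and 3.58 with a pseudocount equal to the median. AT1G68440, AT1G70820 and AT1G56300, also with lows under 29.2, had ranges of 6.47, 6.29 and 6.19, and 4.40, 3.96 and 3.96 with that pseudocount. Among the starch genes, PWD, which phosphorylates glucans for starch breakdown, ranged from 159 ± 23 at 16 h to 1037 ± 3.0 at 24 h (SD, n = 2; adjusted p = 1.0e-06). All 3 tested starch synthesis genes and 2 of the 4 tested starch breakdown genes (DPE1 and PWD) changed over the cycle, also when adjusted over the list alone. SPS4F, a sucrose-phosphate synthase, was the 1 of 4 sucrose synthesis genes that passed, with 842 ± 5.4 at 14 h and 407 ± 40 at 2 h (SD, n = 2; adjusted p = 0.0328). In all, 3613 of 13648 probe sets changed over the time course (26.5%) and 2926 of them by at least 2-fold, with a median range of 1.43 on the log2 scale. With the replicate block 6011 passed. Of the 3613, 586 were highest at 12 h, 484 at 13 h and 479 at 20 h.

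**Figure D1:**
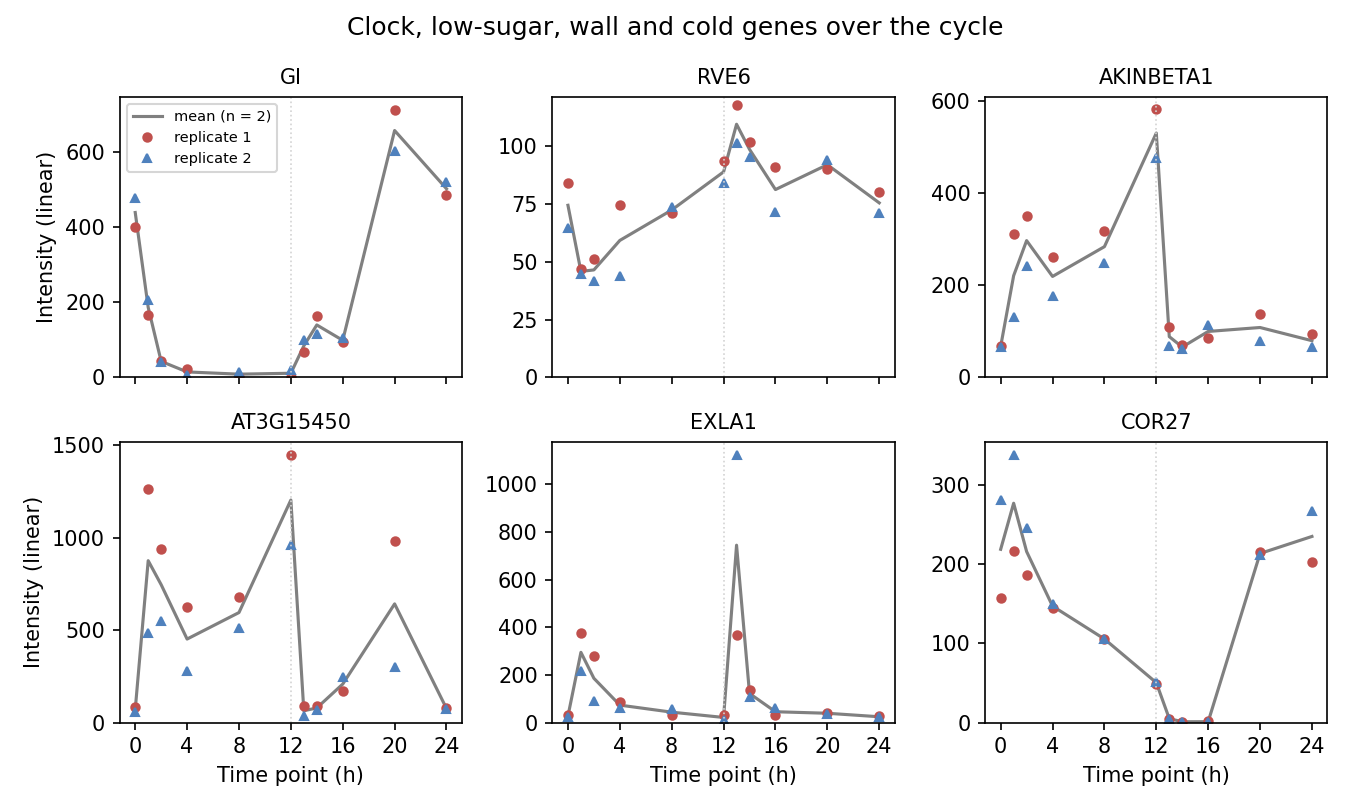
Intensity (linear scale, vertical axis of each panel) against time point in hours for 6 genes, with circles for replicate series 1, triangles for series 2, and a line through the means of n = 2 arrays. GI is low between 4 and 12 h, and AKINBETA1 falls between 12 and 13 h.

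A daily wave was fitted to each probe set to ask at which hour it peaked. GI had a wave of 6.69 ± 0.72 (SE, 22 arrays) on the log2 scale from trough to peak, with its peak at 20.1 ± 0.28 h. AT2G15020 had one of 6.19 ± 0.36 and a peak at 13.2 ± 0.34 h, and AT1G68440 with 5.15 ± 0.59 and a peak at 9.73 ± 0.39 h. CYP71B26, a cytochrome P450, peaked at 18.5 ± 0.31 h. COR15B, a chloroplast protein gene of the cold response, had a wave of 4.27 ± 0.37 with its peak at 22 ± 0.32 h. AFR, an F-box gene of far-red signalling, peaked at 12.5 ± 0.44 h. The genes APL3 and PTST of starch synthesis peaked at 20.1 ± 0.56 h and 20.6 ± 0.41 h. PWD of starch breakdown peaked at 0.83 ± 0.68 h. LCYB, a lycopene cyclase, peaked at 12.8 ± 0.51 h and RVE6, a Myb gene of the clock, at 15.4 ± 0.91 h. All 6 cold and abscisic acid genes had a rhythm, as did 4 of 5 photosystem genes, 3 of 4 Calvin cycle genes and 3 of 6 reference genes. The rhythm passed for 4828 probe sets (35.4%), 1748 of them with a wave of at least 2-fold. Peaks fell in every part of the day, from 316 probe sets between 16 and 18 h to 571 between 22 and 24 h.

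The 13 to 24 h arrays were compared with the 1 to 12 h arrays to find genes that differ between the 2 parts of the cycle. GI was higher at 13 to 24 h by 2.88 ± 0.25 (SE; n = 10 arrays a side; adjusted p = 8.6e-07). In this comparison, here and below, the SE and p rest on the spread between the 2 arrays of a time point. They do not measure the spread over the 10 arrays of a side, which are not replicates of 1 condition. AT3G14200 was higher by 2.99 ± 0.30 and AT2G27420 by 2.77 ± 0.12. THI2.2, a thionin gene, rose by 2.62 ± 0.35 and CYP71B26 by 2.59 ± 0.17, and AT1G73480, AT1G13650, AT5G15950, AT5G35970 and AT2G15020 by 2.25 to 2.42. AT3G15630 fell by 2.84 ± 0.15, AT5G19120 by 2.62 ± 0.25, COR27 by 2.42 ± 0.11 and AT3G15450 by 2.36 ± 0.25. The fall of COR27 did not hold at all of these hours. COR27 stood between 0.8 and 5.1 at 13 to 16 h, but between 202.3 and 267.4 at 20 and 24 h. Its mean intensities were 91.1 at 13 to 24 h and 159 at 1 to 12 h. AT2G15020 stood between 157.3 and 461.2 at 13 to 16 h, but between 0.9 and 11.9 at 20 and 24 h. AT1G49200, AT3G19030, AT5G11070, AT2G20670, AT3G49790 and AT5G08520 fell by 1.78 to 2.03. In all 1467 probe sets were higher and 1768 lower at 13 to 24 h, 186 and 167 of them by at least 2-fold. Without the 8 h and 16 h arrays, left out after seeing the data because their labels disagree, 1001 were higher and 1149 lower. The actin ratio was 2.78 ± 1.43 (SD, n = 10) at 1 to 12 h and 2.36 ± 0.77 (SD, n = 10) at 13 to 24 h.

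Of the gene groups, starch synthesis was higher at 13 to 24 h in all 3 tested genes of the 18 listed. APL3, a subunit of ADP-glucose pyrophosphorylase, rose by 0.95 ± 0.19 (SE; n = 10 arrays a side), PTST, which brings starch synthase to the granule, by 0.56 ± 0.15 and the branching enzyme gene SBE2.2 by 0.33 ± 0.09. The list passed camera (adjusted p = 0.0279), but not with an estimated correlation (adjusted p = 0.135) or without the 8 h and 16 h arrays (adjusted p = 0.0704). The list of genes raised by darkness and low sugar fell (adjusted p = 0.0236; adjusted p = 0.205 with an estimated correlation). Of its 4 tested genes 2 fell, AKINBETA1, a subunit of the SnRK1 energy kinase, by 1.69 ± 0.16 and MCCA, of leucine breakdown, by 0.50 ± 0.10. Adjusted over the list alone, 3 fell. MCCB had a difference of -0.21 ± 0.09 (adjusted p = 0.0984) and IVD of -0.11 ± 0.10 (adjusted p = 0.504). The photosystem list rose (adjusted p = 0.0236; adjusted p = 0.587 with an estimated correlation, adjusted p = 0.0676 with the upper 40% of probe sets, and adjusted p = 0.0984 after quantile normalization, where its median went from 0.33 to 0.14). PSAN, PSBY and PSBW rose by 0.47 ± 0.09, 0.39 ± 0.10 and 0.32 ± 0.09, making 3 of 5, and 4 adjusted over the list alone. LHCB4.2, an antenna protein gene, rose by 1.01 ± 0.10 and LHCB4.1 by 0.34 ± 0.11, without a call for the list of 3 (adjusted p = 0.231). LHCB4.3 stood at -0.26 ± 0.13 (adjusted p = 0.150), lower in both series, and passed with the block (adjusted p = 0.00418). In starch breakdown DPE1, the plastid disproportionating enzyme, fell by 0.60 ± 0.17 and PWD by 0.42 ± 0.10, while AMY1 at 0.15 ± 0.13 and GWD2 at 0.26 ± 0.18 did not pass, and neither did the list (adjusted p = 0.710). The falls of DPE1 and PWD are falls of log values, with mean intensities of 134 in both parts for DPE1, and of 482 at 13 to 24 h and 527 at 1 to 12 h for PWD. That of DPE1 was -0.21 in series 1 and -0.99 in series 2. With the block GWD2 passed as higher (adjusted p = 0.0456).

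No other list passed between the 2 parts of the cycle. None of the 4 sucrose synthesis genes passed (list adjusted p = 0.894), with SPS4F at 0.19 ± 0.10 (SE; n = 10 arrays a side), SPP2 at 0.23 ± 0.21, F2KP at -0.23 ± 0.13 and PGIC at 0.08 ± 0.12. With the block F2KP passed as lower (adjusted p = 0.0136). Of 4 Calvin cycle genes PGKP2 fell, by 0.31 ± 0.06 (list adjusted p = 0.950). Of 4 chlorophyll synthesis genes PORB fell by 0.64 ± 0.21 and GSA1 by 0.25 ± 0.07 (list adjusted p = 0.420). The fall of PORB too is one of log values, -0.19 in series 1 and -1.09 in series 2, and its mean intensity was higher at 13 to 24 h (1004 against 895). In the list of cold and abscisic acid genes COR27 and COR28 fell, COR28 by 1.43 ± 0.16, and the other 4 did not pass. The fall of COR28 is again one of log values, with mean intensities of 72.8 at 13 to 24 h and 78.7 at 1 to 12 h. LTI30 (0.68 ± 0.25) passed as higher with the block (adjusted p = 0.0297) and when adjusted over the list alone. The median of the cold and abscisic acid list was 0.45 and its mean -0.24, so that they differ in sign, and the list's adjusted p was 0.710. RVE6 rose by 0.56 ± 0.10 and LCYB by 0.34 ± 0.08, and ZAT10, a stress zinc finger gene, fell by 0.65 ± 0.21. WRKY53, a transcription factor gene of senescence, stood at -0.48 ± 0.19 (adjusted p = 0.0884), lower in both series, and passed with the block (adjusted p = 0.00122). It also passed as the 1 tested gene of its list, where the p is in effect unadjusted. The 3 photorespiration genes and the 3 ribosomal protein genes did not pass (both lists adjusted p = 0.894), but with the block HPR1 passed as higher (adjusted p = 0.0372) and RPP0B as lower (adjusted p = 0.0433). Of 6 reference genes TIP41L fell, by 0.43 ± 0.11, and the list had an adjusted p of 0.710.

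The first hours after 0 h were compared with 0 h. EXO rose from 27.4 ± 23.1 to 912 ± 5.2 (SD, n = 2) at 1 h, a log2 difference of 5.09 ± 0.58 (SE; adjusted p = 0.000535). The expansin-like gene EXLA1 rose by 3.21 ± 0.55, and AT2G20670, AT5G19120, AT3G15450 and AT2G24550 by 4.17 ± 0.78, 3.84 ± 0.55, 3.42 ± 0.56 and 2.85 ± 0.31. AKINBETA1 rose by 1.53 ± 0.37 at 1 h, 2.06 ± 0.37 at 2 h and 1.62 ± 0.37 at 4 h. The cellulase gene GH9C2 fell by 1.92 ± 0.44 at 1 h and the P450 gene CYP78A9 by 1.03 ± 0.20. GI fell by 3.24 ± 0.56 at 2 h and 4.72 ± 0.56 at 4 h. Its difference of -1.22 at 1 h did not pass over all probe sets (adjusted p = 0.413 in limma). It passed only as the 1 tested gene of its list, where the p is in effect unadjusted. At 4 h ATG8E, an autophagy gene, was higher by 1.91 ± 0.34 and LHCB4.2 lower by 1.08 ± 0.22. RVE6 differed by -0.64 ± 0.22 at 1 h, which did not pass over all probe sets (adjusted p = 0.196), but passed with the replicate block (adjusted p = 0.0420). It also passed as the 1 tested gene of its list, again in effect unadjusted. In all 204 probe sets rose and 28 fell at 1 h, 105 and 54 at 2 h, and 98 and 90 at 4 h. With the block the totals were 655, 621 and 590. The 1 h array of series 2 has the highest actin ratio, and without the 3 arrays of highest ratio, a choice made after seeing the data, 112 rose and 18 fell at 1 h.

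At 4 h against 0 h the tested starch genes, 3 of 18 for synthesis and 4 of 26 for breakdown, were lower as lists in camera. The starch synthesis list fell with a median of -0.97 (adjusted p = 0.0155; adjusted p = 0.124 with an estimated correlation), and its 3 genes passed when adjusted over the list alone but not over all probe sets. PTST had -0.97 ± 0.33 (SE, n = 2; adjusted p = 0.210, and 0.0417 with the block). The starch breakdown list fell with a median of -0.56 (adjusted p = 0.0394; adjusted p = 0.474 with an estimated correlation), with PWD at -0.82 ± 0.22 (adjusted p = 0.0859, and 0.0205 with the block). The photosystem list fell (adjusted p = 0.0326; adjusted p = 0.637 with an estimated correlation), with none of its 5 genes past the test. The list of genes raised by darkness and low sugar rose (adjusted p = 0.0439; adjusted p = 0.300 with an estimated correlation, and 0.0520 with the block), with AKINBETA1 the 1 gene of 4 that passed.

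**Figure D2:**
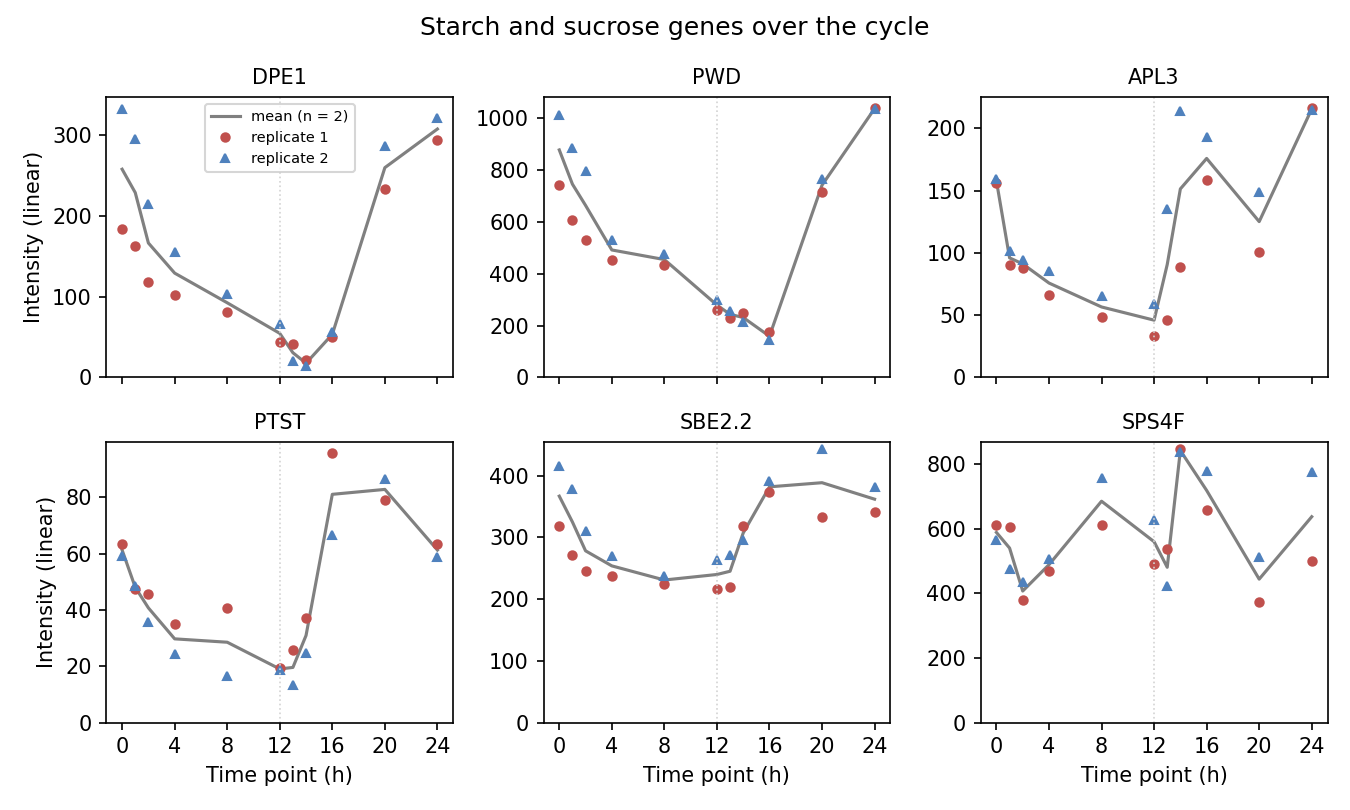
Intensity (linear scale, vertical axis of each panel) against time point in hours for 6 genes of starch and sucrose metabolism, with circles for replicate series 1, triangles for series 2, and a line through the means of n = 2 arrays. DPE1 and PWD are lowest at 14 and 16 h, and APL3 is lowest at 12 h.

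By 8 and 12 h the differences from 0 h had more members. GI fell by 5.35 ± 0.56 (SE, n = 2) at 8 h and 5.17 ± 0.56 at 12 h. AKINBETA1 rose by 2.90 ± 0.37 at 12 h, from 67.2 ± 1.1 to 530 ± 75 (SD, n = 2), and MCCA by 1.42 ± 0.21. DPE1 fell by 1.39 ± 0.38 at 8 h and 2.13 ± 0.38 at 12 h, PWD by 0.93 ± 0.22 and 1.62 ± 0.22. APL3 fell by 1.74 ± 0.42 and PTST by 1.5 ± 0.33 at 12 h. At 8 h these last genes passed over all probe sets only with the block (adjusted p = 0.00557 and 0.00998), as did SBE2.2 at 12 h (-0.60 ± 0.21; adjusted p = 0.00588). Adjusted over the list alone, all 3 passed at 8 h and at 12 h. COR15B fell by 3.30 ± 0.51, COR28 by 2.82 ± 0.35 and COR27 by 1.98 ± 0.25 at 12 h. COR15A, at -2.98 ± 0.94 (adjusted p = 0.0421), differed by -1.05 in series 1 and -4.91 in series 2. It did not pass without 12 h replicate 2 (-1.13; adjusted p = 0.465) or over the time course (adjusted p = 0.0745). AT2G41250 rose by 4.95 ± 0.25, AT1G68440 by 4.45 ± 0.37 and AFR by 4.14 ± 0.61 at 12 h. AT2G20670 and AT2G15020 rose from 4.10 ± 0.99 and 3.30 ± 1.84, within the range of the bacterial controls, to 400 ± 19 and 234 ± 53 (SD, n = 2). The sizes of these rises, 5.64 ± 0.78 and 5.03 ± 0.46, depend on the pseudocount and were 3.31 and 2.65 with one equal to the median. AT1G07050 fell by 5.12 ± 0.30 and AT4G16146 by 4.18 ± 0.19. These 2 genes, GI and COR28 at their falls, and AFR at 0 h were under 29.2 as well. With a pseudocount equal to the median, their 12 h differences were -3.22 for AT1G07050, -3.19 for AT4G16146, -3.24 for GI, -1.61 for COR28 and 2.92 for AFR, and that of GI at 8 h was -3.30. LHCB4.2 rose by 1.2 ± 0.22, CHLM, of chlorophyll synthesis, by 0.82 ± 0.21 and LCYB by 0.81 ± 0.18, while GSA1 fell by 0.56 ± 0.16. At 8 h 485 probe sets rose and 238 fell, and at 12 h 1101 rose and 1015 fell, with totals of 1534 and 3417 under the block. The 12 h array of series 2 has an actin ratio of 4.01, and without the 3 arrays of highest ratio 730 rose and 586 fell at 12 h.

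In the gene lists at 12 h against 0 h, cold and abscisic acid genes fell in 4 of 6 cases, with a median of -2.40 (adjusted p = 0.00180; adjusted p = 0.124 with an estimated correlation). Starch synthesis fell in 2 of 3 genes, and in 3 adjusted over the list alone (list adjusted p = 0.0236; adjusted p = 0.135 with an estimated correlation). Genes raised by darkness and low sugar rose in 2 of 4 cases (adjusted p = 0.0228; adjusted p = 0.186 with an estimated correlation). Starch breakdown, with 2 of 4 genes lower, had an adjusted p of 0.0691.

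**Figure D3:**
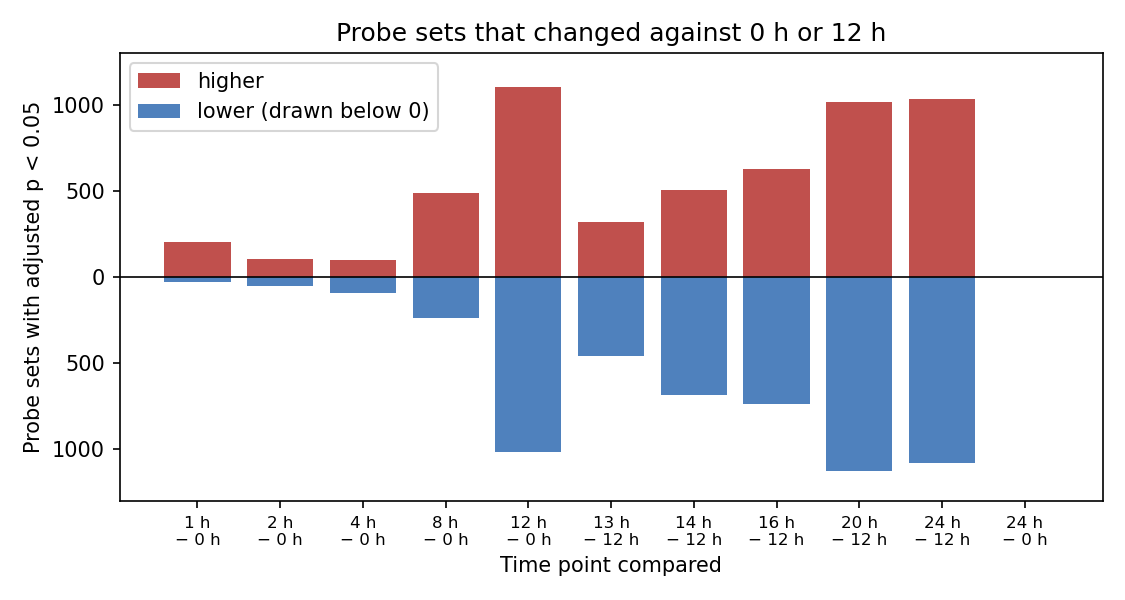
Number of probe sets with an adjusted p under 0.05 (vertical axis, higher above 0 and lower below 0) for each time point against 0 h or 12 h (horizontal axis), from 2 arrays per time point. The totals at 12 h against 0 h and at 20 h and 24 h against 12 h each exceed 2100, and none passed at 24 h against 0 h.

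The hours after 12 h were compared with 12 h. EXLA1 rose from 21.6 ± 13.5 to 745 ± 536 (SD, n = 2) at 13 h, a log2 difference of 4.77 ± 0.55 (SE; adjusted p = 7.2e-05). AT3G14200 rose by 4.47 ± 0.66, AT2G27420 by 3.65 ± 0.28, TBL26 by 2.92 ± 0.53 and GI by 2.83 ± 0.56. AKINBETA1 fell by 2.56 ± 0.37 at 13 h and 2.93 ± 0.37 at 14 h, to 65.9 ± 5.0 (SD, n = 2). MCCA fell by 1.1 ± 0.21 and 1.64 ± 0.21, and ATG8E by 2.80 ± 0.34 at 13 h. AT3G15450 fell by 4.24 ± 0.56, AT5G19120 by 3.89 ± 0.55 and COR27 by 2.59 ± 0.25. The expansin gene EXPA8 fell by 2.02 ± 0.47 at 13 h and PORB by 2.52 ± 0.47 at 14 h. At 16 h CYP71B26 was higher by 4.52 ± 0.37. APL3 rose by 1.56 ± 0.42 at 14 h and 1.89 ± 0.42 at 16 h, and PTST by 1.86 ± 0.33 at 16 h, while PWD fell by 0.80 ± 0.22. At 16 h the starch synthesis list rose (adjusted p = 0.00413; adjusted p = 0.124 with an estimated correlation), with 2 of 3 genes past the test and 3 adjusted over the list alone. The list of genes raised by darkness and low sugar fell (adjusted p = 0.0128; adjusted p = 0.135 with an estimated correlation), in 2 of 4 genes. At 13 h 319 probe sets rose and 460 fell, at 14 h 503 and 686, and at 16 h 625 and 734. The totals with the block were 1520, 2284 and 2476. Without the 3 arrays of highest actin ratio, the 12 h array of series 2 among them, they were 337, 603 and 677.

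The 20 and 24 h arrays were also compared with 12 h. The 12 h arrays serve in the difference from 0 h as well, which by itself makes the signs of the 2 comparisons tend to be opposite. GI rose by 5.75 ± 0.56 at 20 h and 5.37 ± 0.56 (SE, n = 2) at 24 h. DPE1 rose by 2.19 ± 0.38 and 2.44 ± 0.38, and PWD by 1.4 ± 0.22 and 1.88 ± 0.22. PTST rose by 1.91 ± 0.33 and 1.5 ± 0.33, APL3 by 1.39 ± 0.42 and 2.18 ± 0.42. All 6 cold and abscisic acid genes rose at 20 h, among them COR15B by 3.84 ± 0.51, COR28 by 3.48 ± 0.35 and LTI30 by 2.58 ± 0.55. PORB rose by 2.08 ± 0.47 at 20 h. AKINBETA1 fell by 2.29 ± 0.37 and 2.69 ± 0.37, and LCYB by 0.71 ± 0.18 and 0.92 ± 0.18. At 24 h LHCB4.2 fell by 1.17 ± 0.22 and CHLM by 0.95 ± 0.21. AT1G68440 fell by 6.47 ± 0.37 at 20 h and AT2G20670 by 5.72 ± 0.78 at 24 h. In all 1013 probe sets rose and 1122 fell at 20 h, and 1031 rose and 1078 fell at 24 h. With the block the totals were 3256 and 3360, and without the 3 arrays of highest actin ratio, the 24 h array of series 2 among them, 1258 and 816.

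The 24 h arrays were compared with the 0 h arrays, the same point of 2 successive cycles. GI was at 439 ± 55 at 0 h and 502 ± 25 at 24 h, DPE1 at 258 ± 105 and 307 ± 19, PWD at 877 ± 190 and 1037 ± 3.0, and AKINBETA1 at 67.2 ± 1.1 and 79.7 ± 19.7 (SD, n = 2). No probe set passed in limma, with or without the block. At an unadjusted p under 0.05 there were 364 without the block and 764 with it, where 682.4 are expected with no effect. The design does not show that the levels were equal.

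Root genes, measured as a check on the tissue, lay below the filter, with means over all arrays of 13.2 for PYK10, 14.0 for EXPA7 and 24.8 for EXPA18. SPCH of the stomatal lineage (4.03), HSP17.6C (8.05) and HSP22 (25.3) of heat shock, APL4 (13.5), SPP3A (14.0) and XTH33 (39.6) also lay below it and were not tested.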

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

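The test of 5S ribosomal RNA against the actin ratio was chosen only after the result was seen, as were the test of the difference between first-hour changes and the alternatives with the actin ratio and without arrays of doubted hours or quality. The share of opposite signs at 13 h was fixed as a test before it was computed, but after the changes of single genes at 1 h and 13 h had been seen. The other tests here were written down before their results were known.

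A signal appeared in a control probe set outside the comparisons. The 5S ribosomal RNA control had a median of 32.5 over the 11 arrays of replicate series 2 and 4.50 over the 11 of series 1, with every series 2 array (20.7 to 150.6) above every series 1 array (1.3 to 12.6). Bacterial control probe sets had a median of 2.00 and a highest value of 29.2 over 27 probe sets and all arrays, so the lowest series 2 arrays lie within their range. Within series 2 the 5S signal and the actin ratio gave Pearson's r = -0.32 (permutation p = 0.362) and Spearman's rho = -0.17 (permutation p = 0.614, n = 11), and r = -0.33 without the 2 arrays farthest from the median ratio.

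The change in the first hour differed after 12 h and after 0 h. A test of the difference itself (13 h minus 12 h against 1 h minus 0 h) passed for 672 probe sets, 220 in the positive and 452 in the negative direction, and for 1478 with the replicate block. AT2G20670, AT5G19120, AT3G15450, AT2G24550 and AKINBETA1 rose at 1 h and fell at 13 h, with differences between these changes of -7.85 ± 1.1, -7.73 ± 0.78, -7.67 ± 0.79, -5.64 ± 0.43 and -4.09 ± 0.52 (SE, n = 2 arrays per time point). AT3G44450 fell at 1 h and rose at 13 h (4.39 ± 0.25). Of the 204 probe sets that rose at 1 h, 64 fell at 13 h, where independent lists would share 6.88, and 20 rose, where they would share 4.77. A common effect of sampling would move genes the same way at both hours. Of the 232 probe sets called at 1 h, 59.1% had the opposite sign at 13 h and 40.9% the same sign. This argues against a common effect on all of them. It cannot exclude one on some genes, such as the 20 that rose at both hours, and probe sets are not independent. A change between light and dark in opposite directions at the 2 hours stays open as a hypothesis, since the labels do not name the lighting.

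The difference between the 2 parts of the cycle was weighed against 3 other explanations. With the actin ratio as a covariate 4183 probe sets differed, more than the 3235 without it. The ratio differed more between the replicate series, which both hold every time point, than between the parts of the cycle. The replicate block alone gave 4714. The covariate can thus raise the count by removing the spread between the series, so it cannot decide on RNA quality. Quantile normalization gave 3259, so the count hardly depended on which of these scalings was used. Both set the arrays to a common level, so a shift shared by most probe sets would not be seen. Of 100 shuffles of the time labels, the real one included, 1 gave as many, and the highest of the others reached 674. This argues against chance, though 100 shuffles cannot show a share under 1 of 100. The same held for the time course (1 of 100, 3613 against at most 95) and for the rhythm (1 of 100, 4828 against at most 534). Shuffles within each replicate series gave at most 1, 318 and 9, again with 1 of 100 as large. The comparison of the 2 parts was planned, and the time point is the designed factor, with every time point in both replicate series. Which property of the time points the differences follow was not tested.

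The labels disagree on the hour of 4 arrays. The hour of each array was estimated from the rhythms of the other time points, with a root mean square error of 1.39 h over the 18 arrays without a conflict. The arrays called 8 h came out at 4.50 and 4.70 h, under 6.5 h by more than that error, which is consistent with the 5 h of their age tag. The estimate also missed the 20 h arrays, whose labels agree, by 2.90 and 3.10 h, nearly as far as it would have missed 8 h. It placed the 12 h arrays at 9.70 and 9.90 h, so it ran early there as well. The titles go with 8 h: the replicate 2 title names it, and the replicate 1 title number of 5 lies 8 h after its 21 on a clock. Only the age tag gives 5 h, and the estimate cannot decide against 8 h. The arrays called 16 h both came out at 16.5 h, above 15 h by just more than the error. Since the estimate ran late by 2.90 and 3.10 h at 20 h, it cannot by itself decide against 14 h. The titles go with 16 h: the replicate 2 title names it, and the replicate 1 title number of 13 lies 16 h after its 21 on a clock.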

How the results depend on the processing

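Alternatives with the actin ratio or without doubted arrays were chosen after seeing the data, the others before. Of 1157 gene and list values 0 turned direction with a call. Ranges and waves could not turn, nor differences under the block or without the eBayes trend. In planned settings with all arrays, calls of the 1157 were unchanged in 10077 cases, lost in 135 and gained in 104. With 1 array left out, 648 were lost and 97 gained. No pseudocount, a pseudocount equal to the median, no filter, quantile normalization, equal medians and eBayes without a trend kept all 17 counts within 1.5 times. The count at 24 h against 0 h was 0 throughout in limma (364 at an unadjusted p under 0.05). The cause of the changes below was not tested.

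The replicate block raised the counts of changed probe sets to 655 at 1 h, 621 at 2 h, 590 at 4 h, 1534 at 8 h and 3417 at 12 h against 0 h, to 1520 at 13 h, 2284 at 14 h, 2476 at 16 h, 3256 at 20 h and 3360 at 24 h against 12 h, and to 6011 over the time course. It moved no other count over 1.5 times, and ended the list call of darkness and low sugar at 4 h (adjusted p = 0.0520). Array weights gave 298 at 4 h and 496 at 13 h. The actin covariate gave 470 at 1 h, 440 at 2 h, 425 at 4 h, 1244 at 8 h, 1378 at 13 h, 2004 at 14 h and 2151 at 16 h. Without the 3 arrays of highest actin ratio there were 130 at 1 h, 1316 at 12 h, 337 at 13 h, 603 at 14 h, 677 at 16 h, 1258 at 20 h and 816 at 24 h against 12 h. Without the 8 h and 16 h arrays there were 100 at 2 h, 122 at 4 h, and 1149 lower between the 2 parts of the cycle. The number of lists passing between the parts, 3, was 0 with an estimated correlation and 0 with the upper 40% of probe sets, which kept the photosystem list (adjusted p = 0.0676) but too few genes of the other 2 to test them.

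Leaving out 1 array leaves a lone sample, assumed to vary like the other groups. The counts then ran from 32 to 286 at 1 h, 15 to 241 at 2 h, 25 to 198 at 4 h, 262 to 747 at 8 h and 1209 to 2203 at 12 h against 0 h, and from 324 to 815 at 13 h, 555 to 1256 at 14 h, 403 to 1421 at 16 h, 1354 to 2192 at 20 h and 1236 to 2161 at 24 h against 12 h. Without 0 h replicate 1 the counts at 1, 2, 4, 8 and 12 h were 62, 30, 69, 334 and 1209, and without 0 h replicate 2 they were 62, 35, 36, 331 and 1363. Without 12 h replicate 1 they were 471, 677 and 752 at 13, 14 and 16 h, and without 12 h replicate 2 they were 406, 708, 779, 1354 and 1369 at 13 to 24 h. Without replicate 1 of the time point itself they were 32 (1 h), 15 (2 h), 25 (4 h), 308 (8 h), 555 (14 h), 403 (16 h), 1399 (20 h) and 1236 (24 h). Without its replicate 2 they were 241 (2 h), 54 (4 h), 262 (8 h), 324 (13 h), 667 (14 h), 1366 (20 h) and 1285 (24 h). The counts for the time course, the rhythm and the 2 parts of the cycle stayed within 1.5 times.

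Every list call, 12 in all, was lost with an estimated correlation. Adjusted p of further losses are in brackets. The upper 40% of probe sets ended those of photosystem and starch breakdown at 4 h and of cold and abscisic acid at 12 h (0.0676 each), and quantile normalization those of photosystem between the parts (0.0984) and at 4 h (0.0623) and of starch breakdown at 4 h (0.0610). Photosystem at 4 h also ended without a filter (0.0784) and with equal medians (0.0620). Darkness and low sugar at 4 h was lost after quantile normalization (0.0623), with equal medians (0.0607), a pseudocount equal to the median (0.0548) and without the 8 h and 16 h arrays (0.0542), as was starch synthesis between the parts (0.0704). Starch breakdown at 12 h gained a call in 5 alternatives, and cold and abscisic acid at 4 h in 3. Calls ended without 0 h replicate 2 for starch synthesis at 4 h (0.0728) and 12 h (0.0574) and starch breakdown at 4 h (0.468), without 0 h replicate 1 (0.380) and 4 h replicate 2 (0.150) for photosystem at 4 h, without 4 h replicate 1 for starch breakdown at 4 h (0.262), and without 12 h replicate 1 for darkness and low sugar at 12 h (0.0511). Darkness and low sugar at 4 h was lost without either 0 h array (0.168 and 0.0574), 4 h replicate 1 (0.267), or any 1 of the 12, 14 and 16 h arrays (0.0511 to 0.0542).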

Other observations

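The tests of gene families, of genes that rose in both first hours and of the peak of GI were chosen only after the results were seen.

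Beta-tubulin genes, a group of the cytoskeleton formed by gene symbol after seeing the data, were lower at 12 h than at 0 h. TUB1 fell by 1.53 ± 0.40, TUB9 by 1.05 ± 0.17, TUB7 by 0.92 ± 0.17 and TUB6 by 0.64 ± 0.17 (SE, n = 2 arrays per time point), and TUB5 at -0.61 ± 0.24 did not pass (adjusted p = 0.0995). It was the 1 family to pass camera among 29 families in 2 comparisons (adjusted p = 0.00335; adjusted p = 0.383 with an estimated correlation). The median was -0.92 as scaled by the authors, -0.95 after quantile normalization and -0.94 with equal medians. The autophagy genes ATG had a median of -0.29 between the 2 parts of the cycle (8 genes, 4 lower, camera adjusted p = 0.0537; adjusted p = 0.968 with an estimated correlation).

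Some genes rose in the first hour after both 0 h and 12 h. EXLA1 rose by 3.21 at 1 h and 4.77 at 13 h, EXO by 5.09 and 2.16, the peptide hormone gene RALFL33 by 1.31 and 1.2, and AT1G23030 by 1.48 and 1.46 (log2, n = 2 arrays per time point). Their changes at the 2 hours did not pass the test of a difference (adjusted p = 0.322 for EXLA1 and 0.0540 for EXO), which does not show that they were equal.

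A hypothesis on the lighting is that 0 h was the end of the light period, so that 1 to 12 h were dark. GI, known to peak late in the day, had its fitted peak at 20.1 ± 0.28 h (SE, 22 arrays), 8 h after 12 h, where a peak between 6 and 12 h would have argued against it. The list of genes raised by darkness and low sugar was higher at 1 to 12 h, though not with an estimated correlation (adjusted p = 0.205). Title numbers that start at 21 for 0 h may be clock hours. The lighting at each hour was not settled here.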
